A study of Mus musculus with 4 samples.

How the data were processed

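The samples were 4 RNA sequencing libraries from HT22 cells, an immortalised mouse hippocampal neuronal line, with 1 library in each of 4 groups. Per the labels, cells received either a control adenovirus or an adenovirus meant to lower the long noncoding RNA AK046375, 2 h after seeding. They were then kept in normal culture or in oxygen-glucose deprivation (OGD), in which the medium held no glucose and nitrogen took the place of oxygen for 6 h. The labels of the single libraries speak of an adenovirus and a knockdown, while the series title and design text speak of a lentivirus and of overexpression of the same transcript. The library labels were used for grouping, and the wording "labelled knockdown" is kept throughout. A search by name matched 0 gene identifiers in the files to AK046375, and no match by sequence or position was tried. Its level was not analysed here, so the direction of the intervention was not checked.

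Total RNA was fragmented to about 200 bp, turned into cDNA with dUTP marking of a strand, and enriched by 12 PCR cycles, per the labels. The submitters' processing notes name TopHat2 and the mouse build mm10. The versions, the counting tool, the annotation release and whether counting used the strand are not given in the sources used here.

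Per the file headers, the authors deposited for each library a length, an effective length, an expected count, a TPM and an FPKM for each of 47069 genes. The expected counts deposited by the authors were whole numbers and were used as rounded counts. They summed to 26002246 in the control library in normal culture, 23340914 in the library labelled knockdown in normal culture, 27539845 in the control library in OGD and 23327743 in the library labelled knockdown in OGD. FPKM values, the expected count per kilobase of effective length and scaled to the total counts of the library, were computed by the authors and were used as deposited. The TPM column deposited by the authors was not used for ratios; a rescaling of FPKM to equal library sums stood in for it as an alternative. The deposited comparison tables, 1 for each culture condition, give a log2 fold change, a log2 of the mean CPM, a p-value and an adjusted p-value per gene, per the file headers. The authors' tool for these is not given in the sources used here, although the column names are those edgeR writes. A further 4 columns of these tables hold values per library and were not used here.

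The ratio of each gene was computed as the log2 ratio of FPKM + 1 between the 2 libraries of a comparison, so a fold on this scale understates differences of genes near or below 1 FPKM. Genes with a mean of at least 1 FPKM over the 4 libraries were compared, which left 12255. The 4 comparisons of 2 libraries were labelled knockdown over control in normal culture and in OGD, and OGD over normal under each virus. A further comparison was the difference of the knockdown log2 ratios, OGD minus normal. With 1 library per group there is no spread between replicates, so no test between conditions was made and no p-value was computed. Genes were counted as higher or lower at 2-fold or more. For named genes the FPKM fold carries an exact conditional binomial 95% interval from the expected counts. The fold uses the effective length of the gene in each library, so it can be unlike the ratio of counts where these lengths differ. The interval takes the lengths as known. Values of some genes are not reported here, although these genes are part of every count and list median. Reads amplified by PCR without molecular identifiers are not independent molecules, so all intervals cover counting error only, and they compare the libraries, not the conditions. No floor was applied to counts. For scale, a count of 3 at a length of 1 kb corresponds to 0.115 FPKM in the control normal and 0.129 in the labelled-knockdown normal library. In OGD it corresponds to 0.109 FPKM with the control virus and 0.129 with the knockdown-labelled virus.

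Choices made before the data were examined were the unit, the filter, the pseudocount, the 2-fold size, the rule for named genes, the 39 gene lists and most alternatives. Per comparison, the rule named the 12 genes with the largest and the 12 with the smallest log2 ratio among genes at 5 FPKM or more in at least 1 of the 2 libraries, and the 8 largest and 8 smallest for the difference. Small RNAs, predicted genes with placeholder names and pseudogenes with names ending in -ps were left out by name. Up to 4 members of each list with the largest log2 ratio in size were also named, and Mt1, Mt2, Hif1a, Vegfa, Ddit4, Txnip, Hmox1, Ddit3, Fos, Mki67 and Tubb3 were always named. The lists held 965 distinct genes, and lists with at least 3 members passing the filter were summarised, which gave 38 lists. The median of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and said to stand apart below the 2.5 or above the 97.5 percentile. The lists covered HIF targets, glycolysis, glucose-sensing genes, the integrated stress response, endoplasmic reticulum chaperones, cytosolic heat shock, NRF2 targets, metallothioneins, antioxidant enzymes, p53 targets, apoptosis, immediate early genes, NF-kB and inflammation, interferon-stimulated genes, antigen presentation, G1/S, G2/M, replication-dependent histones, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation from both genomes, ribosomal proteins, ribosome biogenesis, autophagy and lysosome, ferroptosis and iron, extracellular matrix, axon guidance, clock genes, virus receptors, housekeeping genes and long noncoding transcripts. Marker lists covered neurons, neural progenitors, astrocytes, microglia, oligodendrocytes, fibroblasts and endothelium. Endothelial markers had 2 measured members, too few to summarise.

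Alternatives were a pseudocount of 0.1 FPKM, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, upper-quartile scaling, rescaling to equal library sums, leaving out small RNAs, predicted genes and pseudogenes, a 1.5-fold size, Spearman in place of Pearson correlation, and random lists without matching. Chosen after seeing the data were CPM with TMM scaling (edgeR), a trend on GC content and transcript length removed from each set of log2 ratios by cubic splines with 7 knots, and correlations within deciles of transcript length. The TMM setting added 1 CPM before the log2 and used no transcript length, so it also shrinks ratios of genes with few counts. GC content came from the reference transcripts for 12217 of the 12255 genes (99.7%). Gene symbols, positions and biotypes came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10, for 46488 of the identifiers. Antisense genes and members of near-identical families (histone clusters, Hspa1a and Hspa1b, ribosomal proteins, nuclear copies of mitochondrial genes) are uncertain, because the way reads were divided among them is not given in the sources used here.

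The code was tested on simulated data made from 12217 genes of each comparison, with 200 genes changed by known folds. Both simulated libraries were drawn with counting error alone from the profile of the same library, without variation between replicates. No length trend was added for the shares of genes that follow. These shares check the code and are not error rates for the real libraries. Simulated 4-fold changes were recovered in 92% of cases in the setting of labelled knockdown over control in normal culture, 88% for the same ratio in OGD, 94% for OGD over normal with the control virus and 86% with the knockdown-labelled virus. At 2.5-fold the shares were 68%, 64%, 82% and 72%, and at 8-fold 94%, 96%, 98% and 96%, in the same order. Unchanged genes passed 2-fold in 0.458%, 0.524%, 0.524% and 0.599% of cases. A simulated length trend with Spearman correlations of 0.81, 0.82, 0.75 and 0.82 was reduced to 0.07, 0.01, 0.07 and 0.04 by the spline removal. The preset limit of 0.05 was therefore missed in the simulations of labelled knockdown over control in normal culture and of OGD over normal with the control virus, and the removal is treated as incomplete. Of 100 lists of 20 genes drawn at random from the real ratios, 10%, 3%, 1% and 7% stood apart. With their medians shifted by 1 they stood above in 100%, 100%, 97% and 66%. Random draws share no length or GC content. They check the code and do not show how often lists of short or long transcripts stand apart through a trend. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors.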

Results

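HT22 cells, an immortalised mouse hippocampal neuronal line, were infected with a control adenovirus or with an adenovirus labelled as knocking down the long noncoding RNA AK046375, and were then cultured normally or deprived of oxygen and glucose (OGD) for 6 h. The sequenced material was total RNA. Each of the 4 groups held 1 library, so no difference below has a replicate check, and intervals in brackets are 95% counting intervals for a pair of libraries. Library totals were 26002246 expected counts for the control virus in normal culture, 23340914 for the library labelled knockdown in normal culture, 27539845 for the control virus in OGD and 23327743 for the library labelled knockdown in OGD. Genes with at least 1 FPKM numbered 11819, 11429, 11619 and 12330 in that order.

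The targeted transcript comes before all other genes in a knockdown design, but the level of AK046375 was not analysed here. A search by name matched 0 gene identifiers to it, and would miss a transcript held under another name. The library labels name a knockdown, whereas the series title names overexpression, so every direction below refers to the library labelled knockdown and not to a checked level of AK046375.

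Expression differed more between culture conditions than between viruses. Across genes, which are not independent replicates, the Pearson correlation of log2(FPKM + 1) was 0.952 between the normal libraries and 0.945 between the OGD libraries. It was 0.879 between normal culture and OGD with the control virus and 0.812 with the knockdown-labelled virus. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1, and the metallothionein genes Mt1 and Mt2, which encode small zinc-binding proteins, together took 0.0811% of counts in the control normal library and 0.174% in the labelled-knockdown normal library. In OGD they took 2.84% with the control virus and 1.78% with the knockdown-labelled virus. Cytosolic ribosomal protein genes took 10.6% and 16.1% of counts in the normal libraries, control before labelled knockdown, and 12.8% and 7.39% in the OGD libraries. Mitochondrially encoded genes took 0.414%, 0.582%, 0.539% and 0.963% in the order control normal, labelled-knockdown normal, control OGD and labelled-knockdown OGD. The count-weighted mean transcript length was 1835, 1545, 1815 and 2153 nt in the same order, so the virus pairs also differed in the length of the transcripts they sampled.

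**Figure D1:**
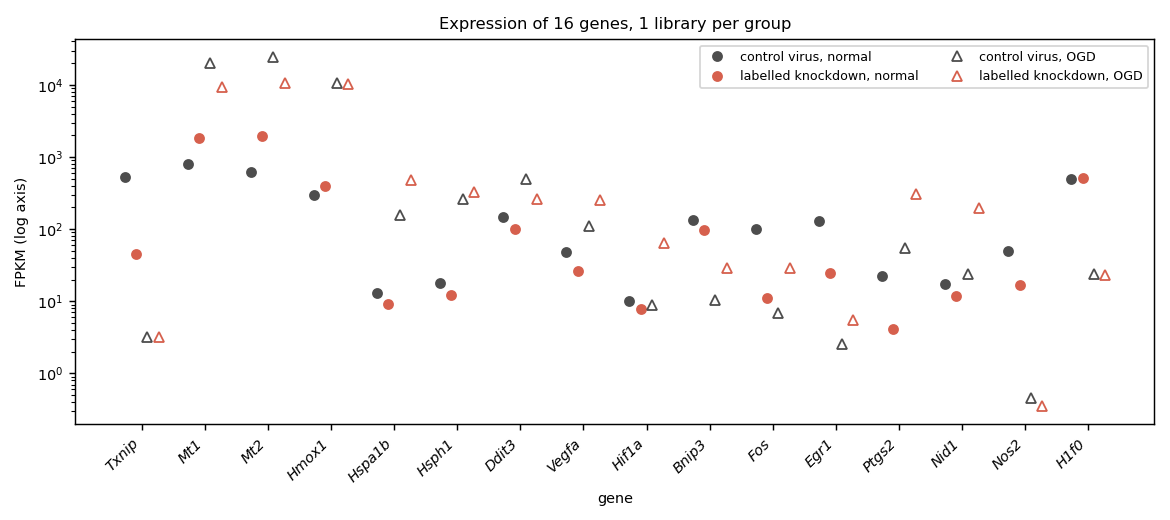
FPKM on a log axis for 16 genes in each of the 4 libraries, with 1 point per library (circles, normal culture; triangles, OGD; grey, control virus; red, labelled knockdown). Txnip stood at 528 FPKM in the control normal library, 45.3 in the labelled-knockdown normal library and 3.16 and 3.21 in the OGD libraries, while Hmox1 stood at 301, 391, 10729 and 10261 FPKM.

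In normal culture the comparison of the library labelled knockdown with its control asked which transcripts differ with the virus against AK046375 in unstressed cells. Txnip, which encodes the thioredoxin-interacting protein that limits glucose uptake, was 11.7-fold lower [11.1 to 12.3], at 45.3 against 528 FPKM. It is a protein-coding gene on chromosome 3, 96557957 to 96561883 in GRCm38. Fos, an immediate early transcription factor gene (chromosome 12, 85473890 to 85477273), was 9.20-fold lower [8.24 to 10.3]. Higher levels were found for the mitochondrial complex I subunit gene mt-Nd3, 5.71-fold [5.35 to 6.10], and for Nhp2, which encodes a protein of box H/ACA small nucleolar particles, 3.79-fold [3.64 to 3.94]. Mt2 was 3.12-fold higher [3.03 to 3.22] and Mt1 2.32-fold higher [2.25 to 2.39], with Mt1 at 0.89 on the log2 scale after rescaling to equal library sums and at 0.52 after removal of the GC and length trend. Vegfa was 1.84-fold lower [1.71 to 1.99], and past 2-fold after rescaling to equal library sums (-1.17). Within 2-fold were Ddit3, 1.48-fold lower, Ddit4, 1.55-fold higher, and Hmox1, 1.30-fold higher, and also Hif1a, 1.30-fold lower, and Tubb3, 1.07-fold lower, whose directions turned with TMM and after trend removal.

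Among the other genes with the lowest ratios were Anxa8, an annexin gene, 9.72-fold lower [8.82 to 10.7], and Rgs16, a regulator of G protein signalling, 11.4-fold lower [9.05 to 14.5]. Serpinb1a was 9.06-fold lower, Slc25a30 8.26-fold lower, Mmp10 9.35-fold lower, Vwa5a 7.25-fold lower and Fam114a1 6.33-fold lower. Genes with the highest ratios also included mt-Nd1, 4.20-fold [4.04 to 4.37], mt-Nd4, 3.92-fold, Rangrf, 3.86-fold, Angptl4, 3.74-fold, and Snhg3, a host transcript of small nucleolar RNAs, 3.62-fold. Snhg9 met the rule for named genes on 4 counts against 1, and no fold is given for it.

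Immediate early genes, a group induced by growth factors and stress, were lower as a list: 13 of 31 measured members were lower by 2-fold or more and 0 were higher, with a median log2 ratio of -0.67 at the 0.12 percentile of random lists. Within it Fos stood at -3.09, the matricellular gene Ccn2 at -2.64, the phosphatase gene Dusp1 at -2.49 and Egr1 at -2.37. NF-kB and inflammatory genes gave 8 of 22 lower and 0 higher (median -0.78, 0.11 percentile, but 3.33 at a filter of 5 FPKM), led by Ptgs2 at -2.20, the inducible cyclooxygenase, and Nfkbiz at -2.07. The extracellular matrix list had 7 of 28 lower and 1 higher (median -0.58, 0.66 percentile), with Thbs1 at -1.98, while Tagln stood at 1.52. Its percentile was 6.67 after removal of the GC and length trend. Glucose-sensing genes had 3 of 6 lower (median -1.04, 0.66 percentile), with Klf10 at -1.46 beside Txnip, and the list no longer stood apart at a filter of 5 FPKM, under TMM scaling or after trend removal.

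DNA replication genes of G1/S were lower, with 12 of 34 members at least 2-fold lower, 1 higher and a median of -0.70 below all 10000 random lists; Mcm6 stood at -2.18, Rrm1 at -2.11 and Cdc6 at -1.93. Mitotic G2/M genes gave 10 of 34 lower and 0 higher (median -0.63, 1.47 percentile), with Dlgap5 at -2.15 and Bub1b at -2.04, but lay at the 24.8 percentile after trend removal. Its member Mki67, a proliferation marker gene, went the other way, 2.32-fold higher in FPKM [2.09 to 2.59] and 0.92 on the log2 scale of FPKM + 1, and past 2-fold with median-of-ratios scaling (1.01), with TMM (1.44) and after trend removal (1.38). Glycolysis genes gave 6 of 18 lower and 0 higher (median -0.61, 0.29 percentile, but 3.30 among unmatched lists), including Pfkp at -1.99 and Pdk1 at -1.47. Endoplasmic reticulum chaperones and unfolded protein response genes gave 7 of 26 lower and 1 higher (median -0.72, 0.04 percentile), including the transport gene Sec24d at -1.95 and the chaperone gene Hspa5 at -1.36. Autophagy and lysosome genes gave 8 of 35 lower and 0 higher (median -0.65, 0.26 percentile), with Atg13 at -1.30 and Lamp2 at -1.25. Clock genes gave 8 of 17 lower and 0 higher (median -0.94, 0.07 percentile; 4.38 after trend removal), with Nr1d2 at -1.37. Housekeeping reference genes gave 5 of 16 lower (median -0.67, 0.10 percentile), with Sdha at -2.21 and Eef1a1 at -1.66. Integrated stress response genes were at the 0.24 percentile (median -0.48), and at the 23.4 percentile after trend removal; 3 members were higher, Fgf21 at 1.53 among them, and 4 were lower. Interferon-stimulated genes stood at the 2.15 percentile (median -0.65), and left the lower tail under every scaling of FPKM tried.

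Higher as lists were the replication-dependent histones, with 22 of 46 members at least 2-fold higher, 0 lower and a median of 0.99 above all 10000 random lists; Hist1h4b stood at 1.89 and Hist1h4i at 1.86. Nuclear-encoded oxidative phosphorylation genes gave 19 of 67 higher and 3 lower (median 0.75, 99.99 percentile), with Uqcrq at 1.77 and Atp5g1 at 1.65 but Sdha at -2.21 and Ndufs1 at -1.65. Of 13 mitochondrially encoded genes, 7 were higher and 1, mt-Atp8 at -2.48, was lower (median 1.05, 99.9 percentile). Cytosolic ribosomal proteins gave 14 of 77 higher and 7 lower (median 0.68, 97.7 percentile), from Rpl38 at 1.48 to Rpl5 at -1.67, and were at the 95.6 percentile after trend removal. These lists of short transcripts stood beside a trend over all genes: the log2 ratio had a Spearman correlation of -0.43 with transcript length and 0.19 with GC content.

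In all, 572 genes were at least 2-fold higher and 1701 lower among 12255, with an all-gene median of -0.27. That split depended on scaling: it was 846 higher and 1209 lower with median-of-ratios scaling (all-gene median -0.15), 1014 and 1011 with upper-quartile scaling (-0.09), 180 and 2940 after rescaling to equal library sums (-0.51), and 974 and 943 with TMM (-0.04). Of 38 lists, 4 stood above, 13 below and 21 within the random lists. None of the list medians named here changed sign under any of those scalings.

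**Figure D2:**
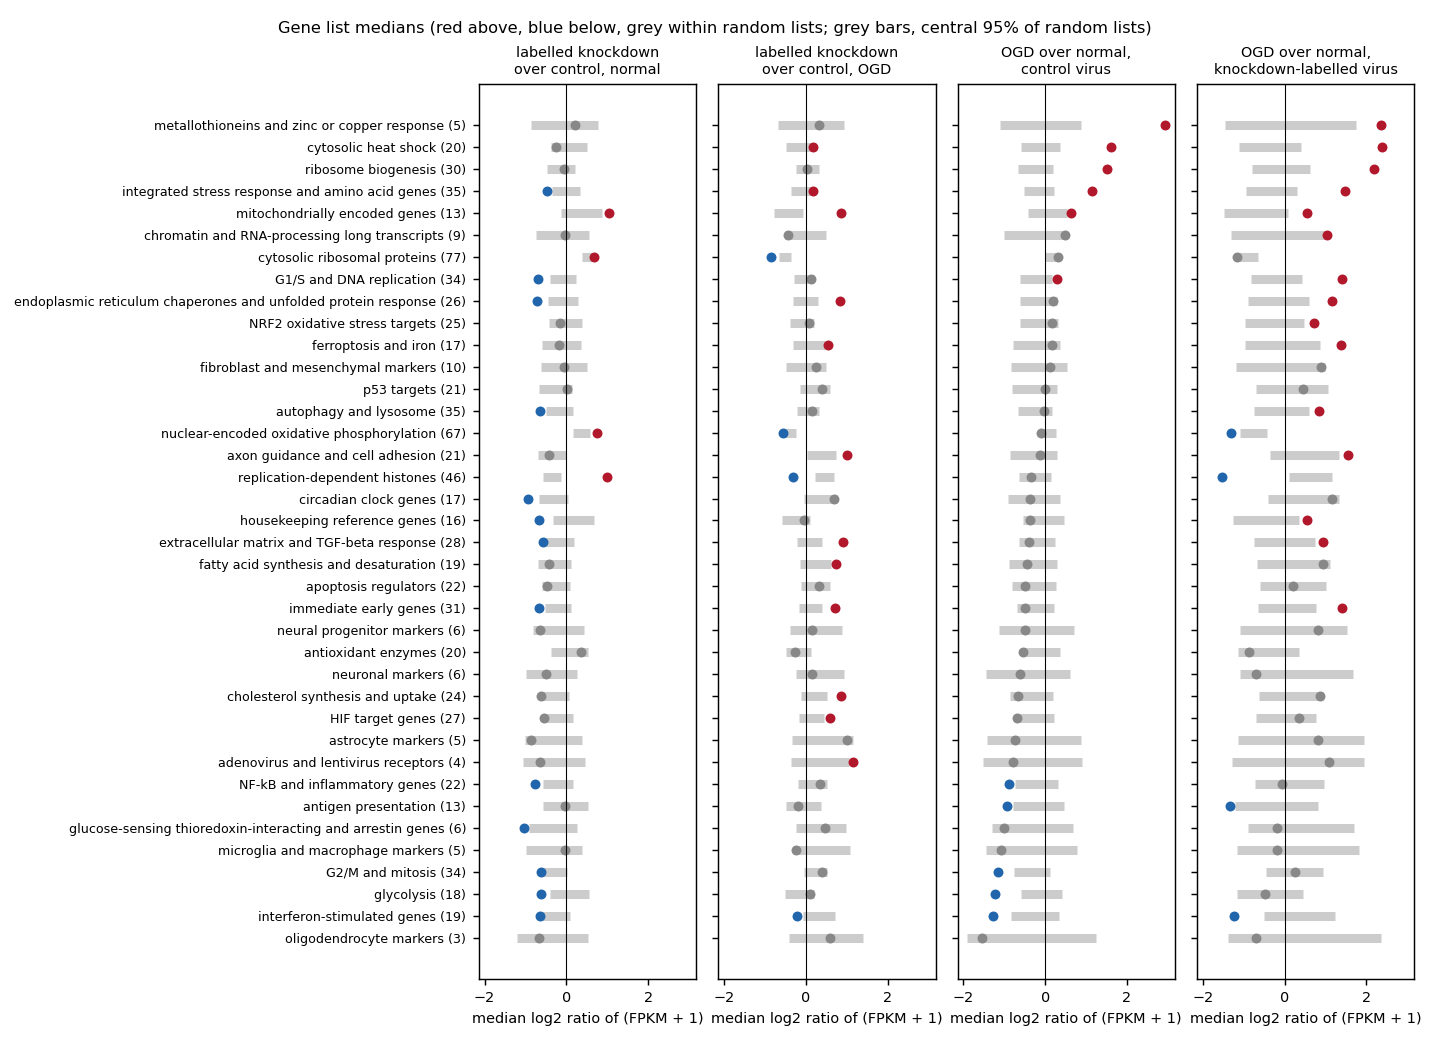
Median log2 ratio of (FPKM + 1) of each of the 38 measured gene lists, with the number of measured members in brackets, in the 4 comparisons of 2 libraries (grey bars, central 95% of 10000 expression-matched random lists; red, above them; blue, below; grey, within). Integrated stress response genes lay at 1.14 and 1.48 in OGD under the control and the knockdown-labelled virus, and glycolysis genes at -1.22 under the control virus.

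Under OGD the same comparison asked which transcripts differ with the AK046375 virus in deprived cells. Nid1, which encodes the basement membrane protein nidogen 1 (chromosome 13, 13437551 to 13512269), was 8.30-fold higher [8.02 to 8.59] in the library labelled knockdown, at 197 against 23.8 FPKM. Hif1a, the oxygen-regulated subunit of hypoxia-inducible factor 1 (chromosome 12, 73901375 to 73947530), was 7.28-fold higher [6.79 to 7.81], at 64.1 against 8.80 FPKM. Irs2, an adaptor of insulin signalling, was 11.6-fold higher [10.1 to 13.3], and Ulbp1, a ligand of the NKG2D receptor, 13.1-fold higher [10.2 to 17.2]. Mt1 and Mt2 were lower, by 2.19-fold [2.17 to 2.21] and 2.27-fold [2.25 to 2.28]. Their log2 ratios were -0.83 and -0.88 after rescaling to equal library sums and -0.55 and -0.66 after trend removal, within 2-fold in both cases.

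Other genes with the highest ratios were the RNA helicase gene Ddx3x, 8.53-fold [8.09 to 9.0], Zfp367, 9.51-fold, the nuclear import gene Ipo7, 11.2-fold, Cyb5d1, 10.0-fold, Tnks2, 7.67-fold, and Ppfibp1, 7.01-fold. Expected counts were 3192 against 984 for Tnks2 and 4407 against 995 for Ppfibp1. The rest of these 2 folds came from effective lengths and library totals that differed between the libraries. The authors' log2 fold changes, based on counts, were 2.06 for Ddx3x and 2.12 for Ppfibp1. Zfp715 was 28.8-fold higher on 427 against 29 counts, and Platr16 43.5-fold higher [11.5 to 361] on 77 against 2 counts. Among the low ratios were those of the chemokine gene Ccl5, 4.34-fold [3.04 to 6.32], the integrin gene Itga6, 3.33-fold [2.82 to 3.93], and Rpp21, which encodes a subunit of ribonuclease P, 2.64-fold. Itga6 stood at -0.56 on the log2 scale of CPM with TMM, where its expected counts were 242 against 365, and Rpp21 at -0.82 after trend removal. Vegfa, the angiogenic growth factor gene, was 2.29-fold higher [2.21 to 2.37], and within 2-fold under upper-quartile (0.95) and TMM scaling (0.79). Ddit3, the stress transcription factor CHOP, was 1.87-fold lower [1.79 to 1.94] and lower by more than 2-fold under the same scalings (-1.13 and -1.18). Txnip was at 3.21 against 3.16 FPKM, 1.02-fold [0.774 to 1.33], a difference not detectable at this depth. Ddit4 was 1.53-fold higher, and Mki67 1.39-fold higher [1.29 to 1.49] but lower after trend removal. Hmox1, 1.05-fold lower, had no steady direction across the alternatives, and Tubb3 was within counting error, 1.09-fold [0.933 to 1.28].

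Extracellular matrix genes were higher as a list, with 13 of 28 at least 2-fold higher, 0 lower and a median of 0.92 above all 10000 random lists; the examples were Thbs1 at 2.54, the collagen cross-linking enzyme gene Lox at 2.11 and Col5a2 at 1.80. Axon guidance and adhesion genes gave 11 of 21 higher and 0 lower (median 1.02, 99.97 percentile), with Efnb2 at 2.48 and Sema3c at 2.24. Immediate early genes gave 11 of 31 higher and 0 lower (median 0.71, 99.99 percentile), with Egr3 at 2.40, Nr4a2 at 2.27 and Fos at 1.94. HIF target genes gave 10 of 27 higher and 0 lower (median 0.60, 99.8 percentile), with Plod2 at 1.75, Kdm3a at 1.54 and Pfkfb3 at 1.52, and stood at the 97.2 percentile of unmatched lists. Cholesterol synthesis and uptake genes gave 8 of 24 higher and 0 lower (median 0.86, 99.99 percentile), with Hsd17b7 at 1.90 and Cyp51 at 1.81. Mitochondrially encoded genes gave 6 of 13 higher and 0 lower (median 0.86, above all 10000 random lists), with mt-Co1 at 2.13 and mt-Nd5 at 2.09.

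Several lists stood above random lists in FPKM but not once the GC and length trend was removed. Endoplasmic reticulum genes gave 9 of 26 higher and 0 lower (median 0.83, above all random lists; 95.4 percentile after removal), with Hspa13 at 2.00 and Hspa5 at 1.73. Fatty acid synthesis genes gave 8 of 19 higher (median 0.75, 99.7 percentile; 97.2 after removal), with the acyltransferase gene Gpam at 2.62. Iron and ferroptosis genes gave 4 of 17 higher (median 0.54, 99.0 percentile; 92.8 after removal), with Ptgs2 at 2.46 and Ncoa4, the ferritin cargo receptor, at 2.16. Virus receptor genes gave 3 of 4 higher (median 1.17, 98.6 percentile; 90.9 after removal), with Itgav at 1.56 and Cxadr at 1.32. Integrated stress response genes had a median of 0.17 (98.8 percentile; 74.2 after removal) that was -0.07 with upper-quartile and -0.25 with TMM scaling. Cytosolic heat shock genes had a median of 0.17 (98.1 percentile; 89.4 after removal) that was -0.07 and -0.14 under those scalings.

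Lower as lists were cytosolic ribosomal proteins, with 15 of 77 at least 2-fold lower, 0 higher and a median of -0.84 below all 10000 random lists, Rplp2 standing at -1.25 and Rpl28 at -1.24. Replication-dependent histones gave 4 of 46 lower (median -0.30, below all random lists), with Hist1h4b at -1.56 (-0.96 with TMM, within 2-fold), and lay at the 92.3 percentile after trend removal. Nuclear-encoded oxidative phosphorylation genes gave 6 of 67 lower (median -0.57, 2.32 percentile; 34.6 after removal), with Atp5e at -1.22 and Uqcrq at -1.16. Interferon-stimulated genes stood at the 0.34 percentile (median -0.21; 22.8 after removal), with 1 of 19 higher, Ifit2 at 1.42, and 0 lower. Long noncoding transcripts, a list fixed as chromatin and RNA-processing long transcripts, had a median of -0.45 within random lists in the main setting. Their percentile was 0.03 after trend removal, 1.05 among unmatched lists and 1.29 without small RNAs, predicted genes and pseudogenes. Over all genes the log2 ratio had a Spearman correlation of 0.57 with length and -0.37 with GC content, opposite in sign to the values in normal culture.

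The count was 1990 genes higher and 279 lower by at least 2-fold, with an all-gene median of 0.26. With upper-quartile scaling it was 1345 and 713 (all-gene median 0.07), with TMM 1184 and 569, and after rescaling to equal library sums 3099 and 99 (0.51). Of the 38 lists, 12 stood above, 4 below and 22 within the random lists.

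OGD was compared with normal culture under the control virus to ask what deprivation does to the transcriptome of these cells. Among genes with high ratios, Mt2 was 39.2-fold higher [38.2 to 40.2], Mt1 25.9-fold [25.3 to 26.5], Hmox1 35.7-fold [34.9 to 36.5], at 10729 against 301 FPKM, and the HSP110 chaperone gene Hsph1 14.5-fold [13.7 to 15.5]. Hmox1 lies on chromosome 8, 75093621 to 75100589, as do Mt2 (94172664 to 94173568) and Mt1 (94179082 to 94180327). Txnip was 167-fold lower [139 to 203], at 3.16 against 528 FPKM. Egr1, an immediate early transcription factor gene, was 51.8-fold lower [45.5 to 59.0], the inducible nitric oxide synthase gene Nos2 111-fold lower [84.3 to 151] and the linker histone gene H1f0 21.2-fold lower.

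Further genes with high ratios were the dipeptidyl peptidase gene Dpp7, 40.6-fold [37.0 to 44.6], the nucleolar GTPase gene Gnl3, 16.1-fold, Gtf2h1, 14.4-fold, Il1rl1, the receptor of interleukin 33, 13.1-fold, Hsp90aa1, 12.1-fold, Hspa1b, 12.4-fold, and the clock repressor gene Bhlhe41, 18.4-fold. Gsta1, a glutathione transferase gene, was 144-fold higher [61.6 to 446] on 764 against 5 counts. Among the low ratios were Ampd3, 33.2-fold lower, Pdgfb, 34.0-fold, Fam131a, 27.8-fold, Aldh1a1, 21.8-fold, Prelp, 19.9-fold, H6pd, 19-fold, Azin2, 18.1-fold, and the mitotic checkpoint gene Bub1b, 17.2-fold. Vegfa was 2.24-fold higher [2.13 to 2.36] and Hif1a 1.16-fold lower [1.05 to 1.27], a direction that turned with median-of-ratios, upper-quartile and TMM scaling. Ddit3 was 3.36-fold higher, Ddit4 1.68-fold lower but not after trend removal, Fos 14.9-fold lower and the neuronal tubulin gene Tubb3 5.66-fold lower. Mki67 was 2.52-fold higher, and within 2-fold on the log2 scale after rescaling to equal library sums (0.91) and after trend removal (0.68).

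Integrated stress response and amino acid genes were higher as a list: 21 of 35 at least 2-fold higher, 0 lower, and a median of 1.14 above all 10000 random lists, with Atf3 at 3.08, Sesn2 at 3.07, Stc2 at 2.90 and Mthfd2 at 2.62. Cytosolic heat shock genes gave 16 of 20 higher and 0 lower (median 1.62), with Hspa1b at 3.53 and Hspa1a at 3.26, which share sequence and are uncertain as single genes. Ribosome biogenesis genes gave 21 of 30 higher and 0 lower (median 1.51), with Nop56 at 2.85 and Ncl at 2.56. Both of these lists also lay above all random lists, as did metallothioneins and zinc response genes, with 3 of 5 higher (median 2.93), among them the zinc exporter gene Slc30a1 at 2.93, and 1 lower, the zinc importer gene Slc39a10 at -2.34. G1/S genes had a median of 0.29 (99.4 percentile), with 4 of 34 higher and 1 lower. NRF2 targets stood within random lists (median 0.18, 92.1 percentile) and above them with TMM (median 0.59, 99.1 percentile), and Gsta1 stood at 5.19, Hmox1 at 5.15 and Gclc, of glutathione synthesis, at 3.32. Mitochondrially encoded genes stood at the 99.1 percentile (median 0.64) and at the 19 percentile after trend removal.

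Glycolysis genes were lower, with 12 of 18 at least 2-fold lower, 1 higher and a median of -1.22 below all 10000 random lists; Pdk1 stood at -2.90, Pfkm at -2.87, Pfkl at -2.84 and the lactate exporter gene Slc16a3 at -2.68. HIF target genes did not stand apart (median -0.69, 3.74 percentile): 6 of 27 were lower, with Bnip3 at -3.55 and Ccng2 at -3.16, and 3 were higher, among them Ndrg1 at 2.10. G2/M genes gave 18 of 34 lower and 3 higher (median -1.15, 0.01 percentile), with Bub1b at -3.84 and Plk1 at -3.50. Interferon-stimulated genes gave 15 of 19 lower and 0 higher (median -1.27, 0.05 percentile), with Irf7 at -2.97. Antigen presentation genes gave 6 of 13 lower (median -0.94, 0.87 percentile, but 3.10 among unmatched lists), with the peptide transporter gene Tap1 at -2.93. NF-kB and inflammatory genes gave 10 of 22 lower and 5 higher (median -0.89, 0.49 percentile), with Cxcl10 at -2.71 and Nfkb2 at -2.52. Immediate early genes went both ways, 10 of 31 higher and 13 lower (median -0.50, 12.4 percentile).

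The count was 1422 genes higher and 2977 lower, with an all-gene median of -0.25. It was 2043 and 2159 with median-of-ratios scaling (all-gene median 0.0019), 2279 and 1978 with upper-quartile scaling (0.07), 1225 and 3254 after rescaling to equal library sums (-0.34) and 2015 and 2354 with TMM. Log2 ratios had a Spearman correlation of -0.03 with length and -0.27 with GC content. Of the 38 lists, 6 stood above, 5 below and 27 within the random lists.

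The same comparison under the knockdown-labelled virus asked how deprivation acts with the virus against AK046375. Il1rl1 was 104-fold higher [93.6 to 117], the inducible cyclooxygenase gene Ptgs2 73.4-fold [66.7 to 81.2] and the orphan nuclear receptor gene Nr4a1 55.4-fold [49.5 to 62.0]. Hspa1b was 53.3-fold higher [49.0 to 58.1] and Hmox1 26.3-fold [25.8 to 26.8]. Hif1a was 8.20-fold higher [7.57 to 8.90], at 64.1 against 7.81 FPKM, and Vegfa 9.46-fold [8.85 to 10.1]. H1f0 was 21.6-fold lower [20.4 to 23], Nos2 48.2-fold [33.7 to 69.4] and Txnip 14.1-fold [11.7 to 17.2].

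Further high ratios were those of the BMP antagonist gene Grem1, 52.6-fold, Hspa1a, 51.8-fold, the keratin gene Krt80, 51.1-fold, Gclc, 39.7-fold, Zfand2a, 37.7-fold, the phosphate transporter gene Slc20a1, 36.1-fold, and Hsph1, 27.1-fold. Low ratios were those of Oxld1, 28-fold lower, Azin2, 20.8-fold, Tmem53, 20.3-fold, Rassf7, 19-fold, Tmem37, 17.1-fold, the cell cycle inhibitor gene Cdkn2d, 16.8-fold, Pigyl, 15.6-fold, and Ppp1r35, 15.4-fold. Mt1 and Mt2 were 5.11-fold [5.01 to 5.20] and 5.54-fold [5.45 to 5.63] higher, Ddit3 2.66-fold higher, Ddit4 1.71-fold lower (past 2-fold with TMM, -1.11) and Tubb3 4.82-fold lower. Fos was 2.62-fold higher [2.31 to 2.99], and within 2-fold with TMM (0.80 on the log2 scale). Mki67 was 1.51-fold higher [1.40 to 1.63] but stood at -1.29 after trend removal.

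As under the control virus, integrated stress response genes were higher as a list, 27 of 35 with 0 lower and a median of 1.48, and so were cytosolic heat shock genes, 15 of 20 with 0 lower (median 2.39), and ribosome biogenesis genes, 18 of 30 with 2 lower (median 2.18). All 3 medians lay above all 10000 random lists. Slc7a1, a cationic amino acid transporter gene, stood at 4.45, Atf3 at 4.36, Hspa1a at 5.37 and Wdr75 at 3.32. Metallothioneins and zinc response genes gave 4 of 5 higher (median 2.35, 99.9 percentile), and NRF2 targets 9 of 25 higher and 4 lower (median 0.73, 99.6 percentile, but 85.4 among unmatched lists), from Gclc at 4.89 to Blvrb at -2.55. Immediate early genes gave 20 of 31 higher and 5 lower (median 1.40, 99.99 percentile), with Nr4a1 at 5.57 and Nr4a2 at 4.52. G1/S genes gave 20 of 34 higher and 2 lower (median 1.39, above all random lists), with Cdc6 at 3.79 and Mcm4 at 3.10 but Tk1 at -2.80. Endoplasmic reticulum genes gave 14 of 26 higher and 2 lower (median 1.17, 99.96 percentile), with Hspa5 at 2.93 and Canx at 2.75.

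Lists that stood above in FPKM but not after trend removal were autophagy and lysosome (median 0.84, 99.6 percentile; 97.1 after removal), ferroptosis and iron (1.37, 99.9; 91.2), extracellular matrix (0.95, 99.5; 88.5), axon guidance (1.55, 99.7; 90.4) and mitochondrially encoded genes (0.55, 99.7; 95.4). In them Gla, a lysosomal galactosidase gene, stood at 3.10, Chac1 at 3.11, Thbs1 at 3.45, Efnb2 at 3.37 and mt-Atp8 at 2.22. Housekeeping genes (median 0.55) stood at the 99.0 percentile, with 7 of 16 higher, 2 lower and the translation factor gene Eef1a1 at 1.98, and at the 69.5 percentile of unmatched lists. Long noncoding transcripts stood just past the limit (median 1.04, 97.53 percentile), with Malat1 at 2.71 and Neat1 at 2.03, and within it under 5 alternatives.

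Nuclear-encoded oxidative phosphorylation genes were lower, 43 of 67 by at least 2-fold with 2 higher and a median of -1.31 below all 10000 random lists, Ndufb4 standing at -2.35 and Ndufv3 at -2.32. Replication-dependent histones gave 33 of 46 lower and 0 higher (median -1.54, below all random lists), with Hist1h2bj at -3.60, and lay at the 2.82 percentile after trend removal. Interferon-stimulated genes gave 12 of 19 lower and 1 higher (median -1.23, 0.02 percentile), with Isg15 at -3.51, and antigen presentation genes 8 of 13 lower (median -1.32, 1.20 percentile), with Tap1 at -3.01. Glycolysis genes lay within random lists (median -0.48, 49.6 percentile), with Slc16a3 at -2.60 and the hexokinase gene Hk2 at 2.56. HIF targets did too (median 0.36, 81.1 percentile), with 13 of 27 higher, Ndrg1 at 4.48 among them, and 6 lower. At a filter of 5 FPKM HIF targets stood above random lists (median 1.04, 99.1 percentile). G2/M genes had a median of 0.26 (50.5 percentile) that was -0.97 after trend removal, below all random lists, with Cenpa at -3.03 and Anln at 2.58.

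The count was 4092 genes higher and 2556 lower, with an all-gene median of 0.32. It was 5345 and 1459 after rescaling to equal library sums (all-gene median 0.75), 3399 and 3255 with TMM (0.01), 4323 and 2361 with median-of-ratios scaling (0.39), and 3891 and 2712 with upper-quartile scaling (0.26). The log2 ratio had a Spearman correlation of 0.47 with length and -0.49 with GC content. Of the 38 lists, 15 stood above, 4 below and 19 within the random lists.

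**Figure D3:**
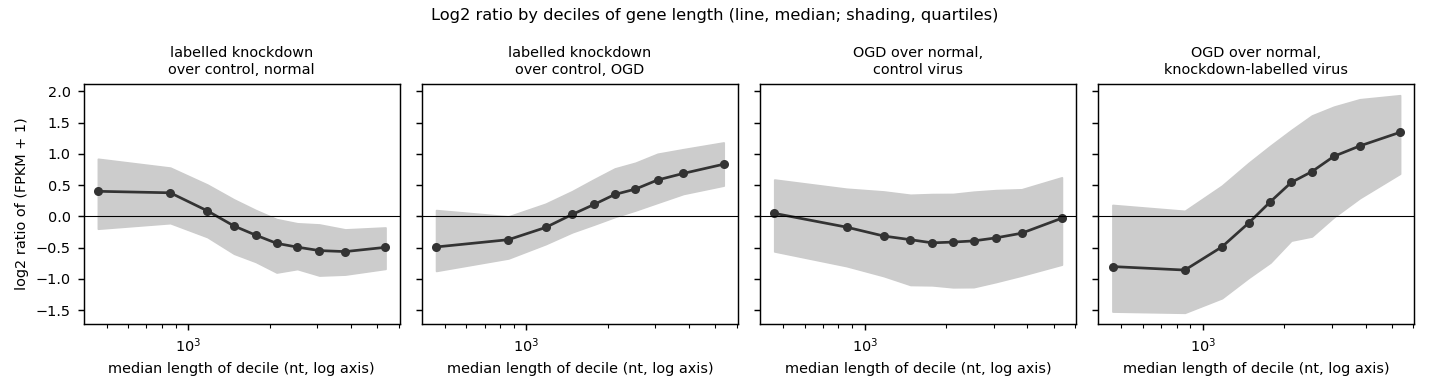
Log2 ratio of (FPKM + 1) by deciles of transcript length, in nt on a log axis, for the 4 comparisons of 2 libraries (line, median of about 1226 genes per decile; shading, quartiles). From the shortest to the longest decile the median went from 0.40 to -0.50 for labelled knockdown over control in normal culture, and from -0.49 to 0.83 for the same ratio in OGD.

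The knockdown ratios in normal culture and in OGD, which share no library, went mostly in opposite directions. Fos was 9.20-fold lower in normal culture and 4.25-fold higher [3.69 to 4.92] in OGD, a difference of 5.03 on the log2 scale. Slc25a30, a mitochondrial carrier gene, differed by 5.33, the protease gene Adamts1 by 5.10, Ulbp1 by 5.06, Ptgs2 by 4.66, Thbs1 by 4.52 and Gnl3l by 4.44. Metallothioneins went the other way, Mt2 by -2.82 and Mt1 by -2.34, as did Uqcrq by -2.93, Bola2 by -2.85, Nhp2 by -2.80 and Cd209c by -2.71. Of the genes lower in normal culture, 541 were higher in OGD, where independent lists would share 276, and 79 were higher in normal culture and lower in OGD, against 13.0. Only 19 were higher in both, against 92.9, and 16 lower in both, against 38.7. Across 12255 genes the Pearson correlation was -0.42 and Spearman's -0.50; after removal of the GC and length trend Pearson's was -0.24. Differences of effects were not tested, since each effect rests on 1 library per group.

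By list, 15 differences stood above, 3 below and 20 within random lists. Besides lists marked below, trend removal took integrated stress response (56.1 percentile), G2/M (62.6), autophagy (82.8), fatty acid synthesis (88.5) and glucose-sensing genes (94.2) out of the upper tail. It placed ribosome biogenesis genes (0) and metallothioneins (1.98) below the limits, and axon guidance genes (97.52) and astrocyte markers (99.3) above them. Immediate early genes gave 22 of 31 at least 2-fold above and 1 below (median 1.98, above all 10000 random lists), and endoplasmic reticulum genes 15 of 26 above and 2 below (median 1.52, above all random lists). Cholesterol synthesis genes gave 16 of 24 above and 0 below (median 1.43, 99.8 percentile; 96.1 after trend removal), and extracellular matrix genes 16 of 28 above (median 1.29, 99.95 percentile). HIF targets gave 16 of 27 above (median 1.18, 99.6 percentile; 93.3 after removal), with Lox at 3.20 and Pfkfb3 at 3.10. Ribosomal proteins gave 55 of 77 below and 2 above (median -1.43), oxidative phosphorylation genes 45 of 67 below and 3 above (median -1.34, 0.02 percentile), and histones 28 of 46 below and 0 above (median -1.24, below all random lists). In all, 4579 genes differed upward and 1554 downward by at least 2-fold (all-gene median 0.61), a split of 2870 and 2374 with TMM (0.10), 3235 and 2336 with upper-quartile scaling (0.23), 3971 and 1893 with median-of-ratios scaling (0.43), and 6543 and 647 after rescaling to equal library sums (1.12).

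OGD ratios under the control and the knockdown-labelled virus went mostly in the same direction. Both were 2-fold or more higher for 1052 genes, among them Hmox1, Mt1, Mt2, Hsph1 and Il1rl1, where independent lists would share 475. Both were lower for 1239, among them Txnip, Nos2 and H1f0, against 621. Lower with the control virus and higher with the knockdown-labelled virus were 274 genes, Fos among them, against 994, and 17 went the other way, against 297. Across genes the Pearson correlation was 0.53 and Spearman's 0.51.

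**Figure D4:**
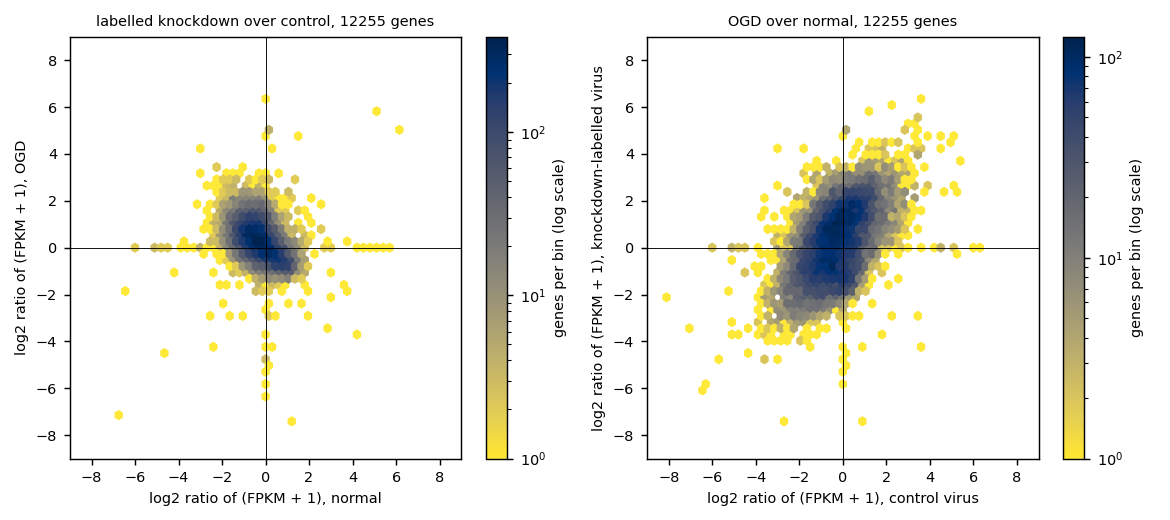
Log2 ratios of (FPKM + 1) of 12255 genes in pairs of comparisons that share no library (left, labelled knockdown over control in normal culture against OGD; right, OGD over normal under the control against the knockdown-labelled virus); colour gives genes per bin on a log scale. The Pearson correlation across genes was -0.42 on the left and 0.53 on the right.

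The authors' deposited table for normal culture lists 1342 genes, 718 higher and 624 lower, with p-values up to 0.05 from single libraries and a median adjusted p of 0.714. Of these, 4 had in the authors' deposited table an adjusted p under 0.05: Txnip (log2 fold change -3.37, adjusted p 0.0174), Rgs16 (-3.24, adjusted p 0.0417), Gm15441 (-3.89, adjusted p 0.00922) and Gm20400 (-4.16, adjusted p 0.0167). Gm15441 and Gm20400, both annotated as antisense, were named after their values were seen, and counts of antisense genes are uncertain here. For OGD the authors' deposited table lists 219 genes, 88 higher and 131 lower, of which 1, Nid1, had an adjusted p under 0.05 (log2 fold change 2.79, adjusted p 0.0346). The authors' deposited table gives Mt1 and Mt2 log2 fold changes of 1.45 and 1.88 in normal culture (adjusted p 0.714 and 0.660), and the authors' deposited table for OGD gives -1.40 and -1.45 (adjusted p 0.643 and 0.613). Every listed gene had the same sign as its FPKM ratio (100%), which is little of a check, since both come from the same libraries and listed log2 fold changes were at least 1.30 in size. The balance of directions was unlike that at 2-fold on FPKM. That was 572 higher and 1701 lower in normal culture, and 1990 higher and 279 lower in OGD. Genes listed in the authors' deposited table for normal culture as higher had a median length of 996 nt and those listed as lower 2633 nt, against 1943 nt for all genes compared. For OGD the authors' deposited table gave 2465 nt for the higher and 567 nt for the lower genes. Genes in both of the authors' deposited tables were 37 higher in normal culture and lower in OGD, 12 lower and then higher, 3 higher in both and 0 lower in both.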

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

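The tests of explanations in this part were all chosen after the result was seen; the rule that picked the genes and lists was set earlier. Among 405 named genes, 85 had log2 ratios of at least 1 in size with opposite signs either for labelled knockdown over control in normal culture against OGD (75 genes) or for OGD over normal under the control against the knockdown-labelled virus (35 genes), and 25 met both. The rule picked genes partly by the size of these same ratios and differences, so these counts do not measure how common opposite ratios are. Among all 12255 genes compared, 620 were opposite for the knockdown ratio and 291 for the OGD ratio. The number given for each gene is the log2 ratio of labelled knockdown over control in OGD minus that in normal culture, which equals the OGD ratio under the knockdown-labelled virus minus that under the control virus. It was positive for 68 genes and negative for 17. After removal of the GC and length trend, 19 of the 75 genes kept opposite knockdown ratios of at least 1 in size, and the difference was smaller by over 1.5 times for 52 of the 85 and larger for 3. With 1 library per group none of these differences was tested.

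Opposite for both effects were the immediate early and matrix genes Fos (5.03), Ccn2 (3.86), Klf10 (2.67), Nfkbiz (3.32), Thbs1 (4.52), Adamts1 (5.10) and Col5a2 (3.06). So were the transporter, carrier and receptor genes Slc25a30 (5.33), Slc39a10 (3.70), Abcc1 (2.80), Npc1 (2.79), Plxna1 (3.13) and Pdgfra (3.16), and the metabolic genes Pfkfb3 (3.10) and Acly (3.32). Others were Sec24d (3.77), Tnks2 (4.23), Ppfibp1 (4.42), Cyb5d1 (4.42), Gnl3l (4.44), Ulbp1 (5.06), the long noncoding 2900097C17Rik (4.76), Bola2 (-2.85) and Rpl29 (-2.16).

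Opposite for the knockdown ratio alone, and lower in normal culture but higher in OGD, were Ptgs2 (4.66), Dusp1 (3.51), Nr4a1 (2.24), Bhlhe40 (2.49), Nr1d2 (3.43), Lox (3.20), Sema3c (3.61), Nrp2 (2.61), Ntn1 (2.15) and Il1rl1 (2.83). In lipid and sterol metabolism these were Cyp51 (2.94), Insig1 (2.75), Gpam (4.34), Elovl5 (3.08) and Acsl3 (2.91), and in the endoplasmic reticulum Hspa5 (3.09), Pdia3 (2.51) and Sel1l (2.83). Cell cycle members were Mcm2 (2.18), Mcm4 (2.78), Bub1b (3.50), Nek2 (2.61), Anln (2.92) and Ccng2 (2.70). Others were Irs2 (4.38), Vwa5a (4.29), Ncoa4 (3.62), Fam114a1 (3.62), Ampd3 (3.38), Dkc1 (2.84), Kdm3a (2.68), Pdk1 (2.55), Lamp2 (2.41), Ndrg1 (2.38), Krt80 (2.36) and Slc20a1 (2.30). Some of these calls rest on effective lengths, since expected counts in OGD differed by less than 2-fold. Labelled knockdown against control, they were 45183 against 38957 for Ndrg1 and 15782 against 11526 for Slc20a1. They were 14599 against 11157 for Mcm2 and 1242 against 829 for Dkc1. How many other calls hold on counts was not computed. Higher in normal culture but lower in OGD were Mt2 (-2.82), Mt1 (-2.34), Hist1h4b (-3.45; its knockdown ratio in OGD was -0.96 with TMM, within 2-fold), Hist1h4h (-2.86), Hist1h4m (-2.71), Uqcrq (-2.93), Ndufs6 (-2.29), Rpl38 (-2.63), Rpl35 (-2.31), Rpl36 (-2.25) and Rpp21 (-2.49). Snhg9 (-4.96) met the rule on 1, 4, 2 and 0 counts in the control normal, labelled-knockdown normal, control OGD and labelled-knockdown OGD libraries, too few for a ratio. With TMM its knockdown ratios were 0.20 and -0.11, a difference of -0.31, and no longer opposite by 2-fold. At such counts the 1 CPM added in that setting shrinks the ratio, whatever the scaling. The same applies to Hist1h4b in OGD, on 9 counts in the labelled-knockdown against 42 in the control library.

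Opposite for the OGD ratio alone were Platr16 (4.44), Rgs16 (3.56), Sdha (3.21), Serpinb1a (3.05), Prrx1 (2.49), Ifit2 (2.14) and Nsdhl (2.07), lower under the control and higher under the knockdown-labelled virus, and Nhp2 (-2.80), Rangrf (-2.64) and Atp5g1 (-2.48), the other way.

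A further 7 gene groups had knockdown medians outside random lists on opposite sides. Immediate early genes (difference 1.98) stood at the 0.12 percentile in normal culture and the 99.99 in OGD, and endoplasmic reticulum genes (1.52) at 0.04 and 100. Extracellular matrix genes (1.29) stood at 0.66 and 100, and integrated stress response genes (0.63) at 0.24 and 98.8, a difference that was -0.12 with TMM. Replication-dependent histones (-1.24) stood at 100 and 0, nuclear-encoded oxidative phosphorylation genes (-1.34) at 99.99 and 2.32, and cytosolic ribosomal proteins (-1.43) at 97.7 and 0. After removal of the GC and length trend, only immediate early genes among these 7 lists were still outside random lists on opposite sides. Other lists became opposite. Ribosome biogenesis genes stood at 99.45 in normal culture and 2.14 in OGD after removal. Glycolysis genes rose to 98.21 in OGD after removal and stayed below the lower limit in normal culture. Metallothioneins and zinc response genes stood at 98.4 and 0.42 at a filter of 5 FPKM, where the list medians (1.21 and -1.13) were the ratios of Mt1 itself.

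The opposite knockdown ratios extended to all genes, with 620 opposite by 2-fold in both conditions and 35 in the same direction. A trend of the fitted form on GC content and transcript length as the whole cause is argued against, since the correlation was still -0.24 after removal. Its 95% bootstrap interval (-0.28 to -0.19) resampled genes, which are not independent, and does not cover differences between libraries. The removal was also incomplete on data simulated from the normal-culture ratio. Within deciles of length the correlation was -0.06 in the shortest and reached -0.41. A bias of another form was not tested. In the fit the trend held 26.5% of the variance of the knockdown ratio in normal culture and 35.2% in OGD. The correlation moved from -0.42 to -0.24 with its removal, so the fitted trend carried part of that correlation. Whether this part is technical cannot be told apart, and counts of opposite genes do not settle it. Among 12217 genes with a GC value, genes opposite by 2-fold fell from 618 to 206, but fewer genes passed 2-fold after removal in either condition, and the overlap of independent lists fell from 289 to 41.1. In tails holding the same number of genes before and after, opposite genes were 618 and 620, a change of 2 (95% bootstrap interval -37 to 43). These tails take in smaller ratios after removal, and genes in the same direction rose from 35 to 66. Virus labels exchanged between the 2 OGD libraries, or between the 2 normal libraries, cannot be told apart from a real reversal here. The level of the targeted transcript was not analysed, since a search by name found 0 identifiers. Correlations between libraries do not decide it. Control and labelled-knockdown normal libraries both lay closer to the control OGD library (0.879 and 0.886) than to the labelled-knockdown OGD library (0.843 and 0.812). Seen from OGD, each library lay closer to the normal library of the other label. The control OGD library stood at 0.886 against 0.879, and the labelled-knockdown OGD library at 0.843 against 0.812. A biological interaction between AK046375 and deprivation stays open and untested.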

How the results depend on the processing

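All counts, lists and correlations rest on 1 library per group, so no library could be left out, and differences smaller than the scaling alternatives move them cannot be read. No paired analysis was run; a model of virus blocked by culture would leave 1 residual degree of freedom and take opposite knockdown ratios as error. TMM scaling, removal of the GC and length trend and length deciles were chosen after seeing the data. No correlation changed sign under the alternatives run, nor did any named gene past 2-fold in the main setting. No list moved to the opposite tail. Mki67, higher but within 2-fold in OGD over normal under the knockdown-labelled virus, stood at -1.29 after trend removal. Where a value moved, the cause was not tested. Median-of-ratios scaling, no filter and Spearman correlation left all counts within 1.5 times. Of 190 list values (38 lists in 5 comparisons), 149 kept their side of the percentile limits after trend removal, with 29 lost and 12 gained. TMM kept 180, median of ratios 188, upper quartile 187, rescaling to equal library sums 185 and a pseudocount of 0.1 FPKM 186. Without a filter 173 were kept, without small RNAs and predicted genes 181, and among unmatched random lists 158. A mean of at least 5 FPKM kept 169, with 9 lost, 7 gained and the rest not measured. Of 157 values of genes named by size or always named, without those named only as list members, trend removal kept 148 on their side of 2-fold, TMM 143 and the other scalings 152 to 156. Opposite calls held less: of 75 named genes with opposite knockdown ratios, 19 kept both past 2-fold after trend removal.

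Counts that moved by over 1.5 times follow, as higher then lower. For labelled knockdown over control in normal culture they were 1014 and 1011 with upper-quartile scaling, 180 and 2940 after rescaling to equal library sums, 974 and 943 with TMM, and 1588 and 3948 at 1.5-fold. The higher count was 362 without small RNAs, predicted genes and pseudogenes, and the lower 586 after trend removal. For the same ratio in OGD they were 3099 and 99 after rescaling, 1184 and 569 with TMM, and 4030 and 1313 at 1.5-fold. The lower count in OGD was 462 with a pseudocount of 0.1 FPKM, 713 with upper-quartile scaling and 113 without small RNAs, predicted genes and pseudogenes, and the higher 1235 at a mean of at least 5 FPKM and 590 after trend removal. For OGD over normal with the control virus they were 2279 and 1978 with upper-quartile scaling and 2558 and 4589 at 1.5-fold. With the knockdown-labelled virus the higher count was 2661 at a mean of at least 5 FPKM and 2040 after trend removal, and the lower 1459 after rescaling. For the difference of knockdown ratios they were 2870 and 2374 with TMM, the higher count 1542 after trend removal, and the lower 2336 with upper-quartile scaling, 647 after rescaling and 2376 at 1.5-fold. The correlation of knockdown ratios was -0.24 after trend removal and between -0.06 and -0.41 within deciles of length.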

Other observations

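The tests of explanations in this part were all chosen after the result was seen. Marker genes of neurons were scarcely expressed: 6 of 32 listed passed the filter, and their median stood within random lists in every comparison, at -0.50 and 0.16 for labelled knockdown over control in normal culture and OGD and at -0.62 and -0.71 for OGD over normal under the control and knockdown-labelled virus. Within this list the neurotrophin gene Bdnf stood at 0.94 and 2.33 in OGD under the 2 viruses while Tubb3 stood at -2.35 and -2.13. Neural progenitor (6 measured), astrocyte (5), microglia (5), oligodendrocyte (3) and fibroblast markers (10) also stood within random lists in the 4 comparisons of 2 libraries in the main setting. Outside the limits under an alternative were astrocyte markers for labelled knockdown over control, at the 98.5 percentile with a pseudocount of 0.1 FPKM and 97.75 among unmatched lists in OGD, and at 1.19 without a filter in normal culture. So were microglia markers for the same ratio in OGD, at 2.20 without small RNAs, predicted genes and pseudogenes, and fibroblast markers in OGD under the knockdown-labelled virus, at 97.78 without a filter. Their medians in OGD under the control virus were -0.50, -0.73, -1.09, -1.54 and 0.12. The gap junction gene Gja1 of the astrocyte list stood at -0.96 and 1.96 for labelled knockdown over control in normal culture and OGD. For the difference of knockdown ratios the astrocyte list stood at the 99.3 percentile after trend removal (median 1.14). Pdgfra, a receptor gene of the oligodendrocyte list, stood at -1.77 and 1.38.

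The lists of apoptosis regulators, p53 targets and antioxidant enzymes did not stand apart in the main setting, but alternatives placed the first and last of these outside the limits. Antioxidant enzymes were at the 2.16 percentile in OGD under the control virus at a filter of 5 FPKM and at 1.90 after trend removal. Among unmatched lists they were at 99.8 and 0.20 for labelled knockdown over control in normal culture and OGD, at 0.55 for OGD over normal under the knockdown-labelled virus and at 1.95 for the difference of knockdown ratios. Apoptosis regulators were at 2.15 in OGD under the knockdown-labelled virus after trend removal and at 99.2 for the difference with TMM. Apoptosis regulators had medians of -0.48 and 0.21 in OGD under the control and knockdown-labelled virus, with Casp9 at -2.76 and -1.94 and Bax at 2.01 under the control virus. The p53 targets stood at 0.45 under the knockdown-labelled virus, with Mdm2 at 3.34 and Plk2 at 2.65. Antioxidant enzymes had medians of -0.55 (3.37 percentile) and -0.88 (16.5 percentile), with 5 and 8 of 20 lower, Prdx5 at -1.11 and -2.10 and Gpx4, the lipid peroxide reductase, at -2.26 under the knockdown-labelled virus but Txnrd1 at 2.19. Clock genes gave Bhlhe41 at 3.55 and 4.06, within a list that did not stand apart in either OGD comparison. The nuclear-retained transcripts Malat1 and Neat1 stood at 2.40 and 2.28 in OGD under the control virus.

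Oxygen deprivation is known to act through HIF, yet HIF targets and glycolysis genes did not stand above random lists in OGD under either virus in the main setting. For HIF targets under the knockdown-labelled virus this depended on the filter, since at a mean of at least 5 FPKM they stood at the 99.1 percentile (median 1.04). If a GC and length trend had hidden a higher level, its removal should place the list median above the upper limit of random lists. Under the control virus the median of HIF targets after removal was -0.34 (95% bootstrap interval -0.78 to 0.10), below the limit of 0.46, and that of glycolysis genes -0.76 (-1.70 to -0.33), below 0.60. Under the knockdown-labelled virus that of glycolysis genes was -0.33 (-0.90 to 0.23), below 0.42. These values argue against a hidden rise in these 3 cases, although the removal was incomplete on data simulated from the ratio under the control virus. HIF targets under the knockdown-labelled virus had a median of 0.25 (-0.81 to 0.95), and a hidden rise cannot be told apart, because the interval holds the limit of 0.44. No biological explanation was tested, since no library with a single deprivation was analysed here.

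Mitochondrially encoded genes were higher in the library labelled knockdown under both conditions, 9 of 13 members by some amount in both, with mt-Atp8 an exception at -2.48 in normal culture. Their GC content of 31.9% to 41.1% lies at the edge of all genes, whose 1st percentile is 38.7% and median 51.1%, so a trend might account for it. In OGD the median was 1.31 after removal (95% bootstrap interval 0.32 to 1.42), above the 0.01 that bounds random lists. That argues against the fitted trend as the whole cause. The fit rests on few genes at this GC content, and the interval takes the 13 genes as independent. A stronger trend at low GC content is therefore not excluded. In normal culture the trend as the whole cause cannot be told apart, with a median of 0.58 after removal (-0.15 to 1.02) beside a bound of 0.55. Nuclear copies of these genes and a difference in the RNA kept for library making stay open and were not tested.

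The log2 fold changes in the authors' deposited tables lay at a median of 0.268 above the ratio of CPM in normal culture and -0.268 in OGD. TMM factors computed here on each pair of libraries differed by 0.268 and -0.268, so the authors' deposited tables hold values on the scale of such a pairwise factor.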
